A study of Homo sapiens with 8 samples.

How the data were processed

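THP-1 cells in 8 conditions were compared by SLAM-seq, in which 4-thiouridine (4sU) taken up by living cells enters new RNA, iodoacetamide alkylates it, and reverse transcription then reads the labelled uridines as T-to-C changes. Cells received a 12 h pulse of 30 uM 4sU, were washed, and were harvested over a chase in excess uridine (3 mM). The protocol gives a medium exchange every 3 h. Labels give 1 library for each of the 7 chase times (0, 20 and 40 min, 1, 2, 8 and 12 h) and 1 library from cells that never received 4sU. Libraries covered 3′ ends (QuantSeq 3′ FWD), with Drosophila S2 RNA added as a spike-in. Spike-in reads were not used here.

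The authors deposited raw counts: all reads per 3′ UTR segment of a transcript, and the converted reads that they call nascent and that are called labelled reads here. The submitters' processing notes name bcl2fastq 2.17.1.14, Trim Galore 0.6.5 and the builds hg19 and dm3. The aligner, the counting tool and the number of conversions required of a labelled read are not given in the sources used here, so a labelled share depends on a threshold that is unknown. No molecular identifiers were used, so intervals cover counting error only.

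Both count tables held 64545 segments from 56570 transcripts, and no segment had more labelled than total reads in any library. Segments of the same gene overlap and count the same reads again: of 31557 segments with more than 50 reads in all, 15274 had counts identical to another segment. Gene counts were therefore taken from the gene's most covered segment. GENCODE 29 named 48045 transcripts (84.9%) by transcript identifier, and 5.65% of the summed counts lay in segments without a match. Left out were 3056 segments on alternative haplotypes or unplaced contigs and 88 genes whose counts equalled another gene's, which leaves 15377 genes with a read. Positions are hg19 starts of the segment as the deposited counts name it. The annotation at hand is on GRCh38 and served for names and for the T content of transcript ends only, never for hg19 coordinates. No segment carried the name of a mitochondrially encoded mRNA or of the listed nuclear long non-coding RNAs.

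Gene counts summed to 2916031 reads without 4sU, 8710635 at 0 h, 8815096 at 20 min, 9542630 at 40 min, 9008796 at 1 h, 8984020 at 2 h, 11224001 at 8 h and 8301030 at 12 h. The labelled share of each library carries a 95% exact (Clopper-Pearson) binomial interval. With 1 library per condition no test between conditions was possible. Tests below measure scatter of the 7 chase libraries about a line in time, with 5 residual degrees of freedom, and the labels do not state whether the times came from separate cultures.

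Decline of the label was tested in edgeR 4.0.16 (R 4.3.3) with a quasi-likelihood fit of labelled counts against hours, offset by the log of the gene's own total in the library. Genes entered with a mean total count of at least 50 and at least 20 labelled reads in all, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. Half-lives come from a binomial maximum-likelihood fit of the labelled share as background plus an exponential, with background set to the gene's share without 4sU, shrunk towards that library's overall share with 100 prior reads. A half-life counted as resolved when the decline was called, the fitted excess at 0 h was at least 10 reads, the standard error of the log rate was at most 0.5, and the value lay between 0.25 and 24 h. Standard errors were widened where the scatter exceeded binomial error. These half-lives describe the labelled share of the gene's own reads, so dilution by new unlabelled RNA counts as decay and a change of total level shifts them.

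The 24 gene lists were immediate-early and feedback genes, leukaemia and haematopoietic regulators, zinc-finger ZNF genes, cytoplasmic ribosomal proteins, nuclear-encoded respiratory chain, mitochondrially encoded mRNAs, glycolysis, mitosis, DNA replication, inflammatory cytokines and NF-kB response, apoptosis regulators, p53 target genes, integrated stress response (ATF4) genes, cholesterol synthesis and uptake, heat shock and chaperones, lysosome and cathepsins, myeloid granule and surface markers, snoRNA host and NMD-prone transcripts, transcription elongation and co-activators, mRNA decay machinery, nuclear-retained long non-coding RNAs, interferon-stimulated genes, markers of lymphoid, erythroid and epithelial cells, and replication-dependent histones. List medians of half-lives were placed among 10000 random lists matched on mean count. limma 3.58.1 camera compared each list with the other genes on log2 of the labelled share against hours, with a preset correlation of 0.01 and again with the correlation estimated, adjusted over the lists.

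Total levels were fitted against hours in edgeR with TMM factors for genes with a mean count of at least 20, and changes are given as log2 over 12 h. Levels at 0 h and without 4sU were compared as ratios of CPM (counts scaled to a common library size) with exact conditional counting intervals for genes with a mean count of at least 100. Where the library without 4sU held no read, the lower end of the interval is given as the least fold. List medians leave such a gene out unless stated, and the figure draws it with 3 reads for that library. Library-size scaling moved the median change over all genes to 0.18 on the log2 scale, against 0.02 with TMM and -0.00 with DESeq2 size factors.

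Lists, the tests of the main comparisons and the rule for named genes were set before the data were examined, and tests of explanations written later are named as such in the closing section. That rule took the 6 shortest and 6 longest resolved half-lives among genes with a mean count of at least 200 and a standard error of the log rate of at most 0.25, a fixed set of anchors (MYC, MYB, MCL1, HOXA9, MEIS1, CDK6, BCL2, FOS, JUNB, IER2, ACTB, GAPDH, LYZ), and up to 2 of the fastest and 2 of the slowest members per list. Those list members had a mean count of at least 100. For total levels the rule took the 8 largest called changes in each direction among genes with a mean count of at least 100, and up to 3 members per list with the lowest p. For the comparison without 4sU it took the 5 genes in each direction whose interval lay farthest from 1. List members named in that last comparison were chosen after their values were seen. A few list members that the rule picked are not reported here.

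Alternatives covered offsets and size factors (TMM, DESeq2 1.42.0, library size), DESeq2 in place of edgeR, count filters, background, amplitude, weights and denominator of the decay fit, the pseudocount of camera, a 0 to 2 h window, the rank of the time, the 20 min library in place of 0 h, addition of the library without 4sU as another 0 h, and each chase library left out in turn. Added after seeing the data were a 1 to 12 h window, the sum of a gene's distinct segments, and a 0 to 2 h window for total levels. Rules for outlying samples and for differences between groups need replicates and were not applied. On simulated data of the same depth, the total-level test recovered 24.2%, 89.6% and 100% of changes of 0.5, 1 and 2 (log2 over 12 h) with 4 false calls among 10643 genes, and the decline test 6%, 43.3% and 95.5% with 0 false calls among 9400. Simulated half-lives of 0.5, 1, 2, 4, 8 and 16 h came back with medians of 0.50, 0.99, 1.97, 3.99, 7.98 and 15.9 h, and 95% intervals covered the true value in 86.0% to 92.9% of genes. These shares were simulated from the fitted model, a decline from 0 h, so bias from other courses of the label was not measured. Further work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.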

Results

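The series measured RNA decay in THP-1, a human line grown from acute monocytic leukaemia that carries the KMT2A-MLLT3 fusion. RNA was labelled with 4sU for 12 h and the label was then chased with uridine, and T-to-C changes in a read mark RNA made while 4sU was present. There was 1 library without 4sU and 1 library at each of 7 chase times, and no condition was replicated. Deposited counts over overlapping 3′ UTR segments summed to between 7046260 (no 4sU) and 27773214 (8 h) per library. With each gene represented by its most covered segment, the library without 4sU held 2916031 reads in 12377 genes, and chase libraries held from 8301030 (12 h) to 11224001 reads (8 h) in 13538 to 13811 genes.

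Whether the label could be told from background was asked in each library alone. At the end of the pulse, 66.5% of MYC reads, 59.48% of reads for the median immediate-early gene and 9.37% of reads for the median cytoplasmic ribosomal protein gene were labelled. MYC is the growth-promoting transcription factor, and its labelled share was 0.34% after 12 h of chase. Over all genes the labelled share was 30.6% at 0 h (95% exact interval 30.58 to 30.64) and 5.53% at 12 h (5.51 to 5.54), against 0.0121% without 4sU (0.0109 to 0.0135, 354 labelled reads). Through the first hour the share was level, with 30.1% at 20 min, 30.7% at 40 min and 30.2% at 1 h, and was 27.1% at 2 h and 10.8% at 8 h. The median gene tested for decay had 44.5% of its reads labelled at 0 h, and the middle 80% of genes lay between 17.3% and 64.4%. Without 4sU, 192 genes had any labelled read, and 7 genes exceeded 5% with at least 3 labelled reads.

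**Figure D1:**
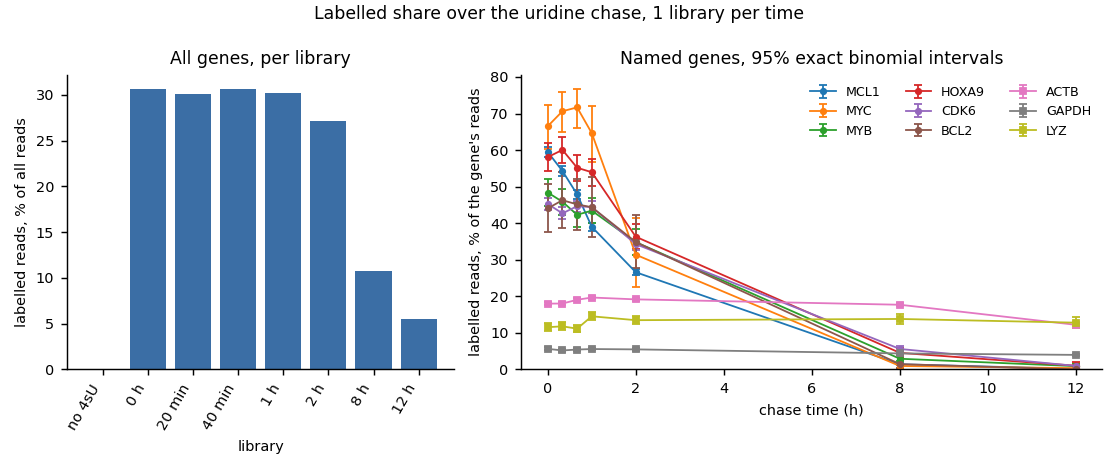
Labelled reads as a percentage of all reads in each library (bars), and of the gene's own reads for 9 named genes against chase time in hours (points, with 95% exact binomial intervals; 1 library per time). The share stayed between 30.1% and 30.7% through the first hour and reached 5.53% at 12 h, and MYC and MCL1 lost their label while ACTB, GAPDH and LYZ kept most of it.

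How fast each mRNA lost its label was the main question of the design. Among genes with a mean count of at least 200 and a standard error of the log rate of at most 0.25, the shortest resolved half-lives belonged to SCAF11, an arginine/serine-rich splicing factor (0.72 ± 0.14 h, SE), to IER3, a stress-response gene (0.96 ± 0.10 h), to SOCS3, a feedback inhibitor of JAK-STAT signalling (1.06 ± 0.26 h), to PTGER4, a prostaglandin E2 receptor (1.06 ± 0.09 h), to JUNB, an AP-1 transcription factor (1.08 ± 0.16 h), and to NFKBIA, the inhibitor that holds NF-kB in the cytoplasm (1.10 ± 0.12 h). The longest resolved half-lives lay close to the limit of 24 h, and genes above that limit or without a called decline are not ranked here. They belonged to UBB, a polyubiquitin gene (23.97 ± 5.11 h), the ribosomal protein gene RPS26 (23.77 ± 3.77 h), and CRIP1, a LIM-domain protein whose counts equal those of AL928654.3 (23.71 ± 4.33 h). Next were the surface glycoprotein CD99 (23.16 ± 4.83 h), UQCR10 of respiratory complex III (23.01 ± 5.74 h) and the endoplasmic reticulum chaperone CANX (22.04 ± 5.02 h). Among genes known in this leukaemia, MCL1, which blocks apoptosis, had a half-life of 1.56 ± 0.07 h, MYC 1.89 ± 0.43 h, BCL2 1.94 ± 0.36 h, MYB 2.15 ± 0.23 h, HOXA9 2.23 ± 0.22 h and the cell-cycle kinase CDK6 2.64 ± 0.34 h. The immediate-early genes FOS and IER2 had 1.88 ± 0.28 h and 1.39 ± 0.20 h. These values describe the labelled share. Labelled reads themselves went from 64 at 0 h to 1548 at 40 min for FOS, from 46 to 347 at 1 h for SOCS3 and from 177 to 318 at 20 min for IER2, so there the fit does not follow the RNA present at 0 h. These genes are examples, and the same can hold for other fast genes given here. The label of ACTB and GAPDH declined (adjusted p = 0.00792 and 0.0288, edgeR), with half-lives above 24 h. LYZ, which encodes lysozyme, had 11.6% of its reads labelled at 0 h and 12.8% at 12 h (adjusted p = 0.615, edgeR), and MEIS1 had 2 reads in all and was not tested.

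In edgeR, the label declined in 8957 of 9402 genes tested (95.3%), and 443 genes passed in neither direction. The adjusted p was 1.07e-12 for SCAF11, 5.73e-14 for IER3 and 3.39e-14 for NFKBIA, and 0.0394 for CRIP1, the weakest call among the named slow genes. The labelled share rose in 2 genes, named here after their values were seen: GAL, the neuropeptide galanin (20.7% at 0 h to 34.8% at 12 h, adjusted p = 0.00989), and MT1H, a metallothionein (29.1% to 39.5%, adjusted p = 0.0269). Resolved half-lives of 8832 genes had a median of 2.72 h, with 10% below 1.81 h and 10% above 6.63 h. Of these genes, 1565 (17.7%) had half-lives under 2 h, 5071 (57.4%) from 2 to 4 h, 1593 (18.0%) from 4 to 8 h and 603 (6.8%) above 8 h. A further 34 declining genes lay above 24 h and 91 were unresolved for other reasons. The fit lets the share fall from 0 h on, although over all genes it was level through the first hour. Over 1 to 12 h alone the median half-life was 2.34 h. In the median gene tested the variance about the fit, any misfit of the curve included, was 3.74 times the binomial variance (Pearson dispersion). At 8 h the median of all genes tested was 14.1% of the labelled share of the 0 to 40 min libraries. Among them the median of the genes without a call was then 98.7%. Across genes, which are not independent replicates, genes with more label at 0 h had shorter half-lives (Spearman's rho -0.52).

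On the hg19 build the measured 3′ UTR segments begin at position 46348517 of chromosome 12 for SCAF11 (minus strand), 30710976 of chromosome 6 for IER3 (minus), 76352864 of chromosome 17 for SOCS3 (minus), 40692481 of chromosome 5 for PTGER4 (plus), 12903630 of chromosome 19 for JUNB (plus), 35870717 of chromosome 14 for NFKBIA (minus) and 128753205 of chromosome 8 for MYC (plus). Among slow genes they begin at 16285912 of chromosome 17 for UBB, 56437939 of chromosome 12 for RPS26 and 179155646 of chromosome 5 for CANX (all plus). With the 0 to 2 h libraries alone, the half-lives of 68 of 94 genes picked by the naming rule lay above the 95% interval of the main value, and those of 2 below it. The half-life was then 3.29 h for MYC, 3.09 h for HOXA9, 4.48 h for MYB, 5.67 h for CDK6 and 6.01 h for BCL2. Among slow genes it was 8.03 h for CRIP1, 16.3 h for RPS26, 183 h for CD99 and 292 h for UBB, and the fits for UQCR10 and CANX ran to their limit of 1000 h. Without the 12 h library the half-life was 48.0 h for UBB, 44.4 h for CANX, 44.0 h for UQCR10 and 35.9 h for CD99. With the CPM of labelled reads in place of the gene's own total the half-life was 11.3 h for UBB, 11.7 h for RPS26, 12.7 h for CANX, 12.9 h for UQCR10, 40.0 h for CRIP1, 1.04 h for MYC, 2.09 h for MCL1 and 2.24 h for SOCS3 (19 of 94 named genes longer and 15 shorter than the main interval). With the amplitude fixed at the 0 h value it was 1.12 h for FOS, and with all segments summed it was 1.86 h for SCAF11.

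Which functions decay fast was asked with gene lists. Immediate-early and feedback genes had a median half-life of 1.53 h (interquartile range 1.39 to 1.71 h, 35 resolved of 37 tested), against 2.96 h for genes of like abundance, below all 10000 matched random lists (percentile 0.00). All 37 declined, and the median gene kept 2.00% of its labelled share of the 0 to 40 min libraries at 8 h. In some members labelled reads rose after the wash. They went from 7 at 0 h to 261 at 40 min for DUSP1 and from 107 to 480 at 1 h for JUN. The falling share of such genes does not follow the RNA present at 0 h. Over the whole chase, camera on the log share did not separate the list from other genes (adjusted p = 0.15 by limma camera, 8.08e-13 to 0.938 over 11 alternatives). It did over 0 to 2 h alone (8.08e-13) and without the 8 h or the 12 h library (0.00721 and 1.54e-06). Late shares of these genes were very low, with a median of 0.77% left at 12 h, where camera's pseudocount can flatten a straight slope. The missing call is therefore no evidence that the list decayed like other genes. Leukaemia and haematopoietic regulators had a median of 2.03 h (1.81 to 2.41 h) with 30 of 30 declining, at percentile 0.00 and against 3.02 h for matched genes. Over the 0 to 2 h libraries alone its median lay above that of all genes resolved over that window (0.20 log2, 22 members). Those were 2822 genes in place of 8832. GFI1, a repressor in myeloid differentiation, had 1.59 ± 0.18 h, CEBPD 1.63 ± 0.11 h and the ETS factor FLI1 2.87 ± 0.38 h. Camera called this list faster (adjusted p = 0.00057), with adjusted p = 0.732 with an estimated correlation (8.99e-05 to 0.732 over 11 alternatives). Zinc-finger ZNF genes, most of them DNA-binding repressors, declined in 272 of 272 with a median of 1.96 h (1.68 to 2.31 h, percentile 0.00). ZNF394 had 1.00 ± 0.20 h and ZNF428 6.98 ± 0.83 h. The ZNF call (adjusted p = 0.00748) was lost with adjusted p = 0.732 with an estimated correlation and 0.206 with a larger pseudocount (2.76e-11 to 0.732 over 11 alternatives).

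Inflammatory cytokines and NF-kB response genes declined in 21 of 21 with a median of 1.93 h (1.53 to 2.54 h, percentile 0.00). TNF had 1.17 ± 0.17 h. Camera gave adjusted p = 0.0837 (0.0264 to 0.732 over 11 alternatives, the lowest without the 12 h library). p53 target genes declined in 19 of 19 with a median of 1.96 h (percentile 0.01), from 1.20 ± 0.15 h for GADD45B and 1.39 ± 0.28 h for the anti-proliferative BTG2 to 5.02 ± 0.58 h for CCNG1, and camera gave adjusted p = 0.15 (0.00031 to 0.732 over 11 alternatives, 0.0455 without the 8 h and 0.0139 without the 12 h library). Transcription elongation factors and co-activators declined in 30 of 30 with a median of 2.03 h (percentile 0.00), among them AFF1 of the super elongation complex (1.57 ± 0.20 h) and CCNT2, a cyclin partner of CDK9 (1.73 ± 0.31 h). At the slow end of the list CCNC had 3.72 h and CCNK 4.68 h. Their camera call was adjusted p = 0.00455, and adjusted p = 0.732 with an estimated correlation (8.37e-05 to 0.732 over 11 alternatives). Apoptosis regulators declined in 24 of 24 with a median of 2.26 h (percentile 1.09), including BMF, a BH3-only protein (1.51 ± 0.17 h), and cytochrome c, encoded by CYCS (6.0 ± 0.91 h, 30.1 h over 0 to 2 h alone). That call (adjusted p = 0.0361) was absent without the 2 h library (0.0545) and gave adjusted p = 0.732 with an estimated correlation (0.0212 to 0.732 over 11 alternatives). mRNA decay machinery declined in 41 of 41 with a median of 2.47 h (percentile 1.37), and the deadenylase subunit CNOT4 had 1.61 ± 0.22 h. At its slow end EXOSC5 had 10.7 h and PABPC1 14.6 h, each with a fit at the limit of 1000 h in some alternative. Over 0 to 2 h alone the median of this list was level with that of all genes resolved over that window (0.00 log2, 21 members). Camera gave adjusted p = 0.0142, and adjusted p = 0.732 with an estimated correlation (0.00897 to 0.732 over 11 alternatives).

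At the slow end, the label declined in 9 of 77 cytoplasmic ribosomal protein genes, 4 when adjusted over the list alone, and the 7 resolved half-lives had a median of 17.3 h (10.8 to 18.4 h, percentile 99.98), against 4.61 h for matched genes. RPL7 had 18.63 ± 3.11 h and RPL13A 9.48 ± 1.23 h (12.6 h and 5.43 h on CPM). The median gene of this list kept 104% of its labelled share of the 0 to 40 min libraries at 8 h and 91.7% at 12 h. With labelled CPM in place of the share it kept 84.98% and 68.85%, totals having fallen in 75 of 78 of these genes. With CPM the median half-life of the list over that of all genes was 1.82 on the log2 scale in place of 2.67, and it was 2.01 to 2.75 leaving out each chase library. Camera called the list slower with adjusted p = 1.42e-122, and adjusted p = 0.0452 with an estimated correlation (5.51e-131 to 0.0452 over 11 alternatives), the 1 list of 12 whose call held both ways. Ribosomal protein genes have many processed pseudogenes, and how shared reads were placed is not given in the sources used here. Genes of the nuclear-encoded respiratory chain declined in 41 of 80 (36 adjusted over the list alone) with a median of 13.1 h over 36 resolved genes (6.76 to 15.9 h, percentile 100). Over that of all genes this median was 2.27 on the log2 scale, and 1.65 without the 12 h library. UQCRFS1, the Rieske iron-sulphur subunit, had 2.97 ± 0.44 h (13.1 h over 0 to 2 h alone), NDUFS1 of complex I 3.40 ± 0.16 h and UQCR10 23.01 ± 5.74 h. Camera gave adjusted p = 1.42e-47, and adjusted p = 0.195 with an estimated correlation (1.03e-54 to 0.195 over 11 alternatives).

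Lysosome and cathepsin genes declined in 22 of 26 with a median of 7.06 h (5.55 to 10.7 h, percentile 100). Its fast members named were CTSC, a protease that activates granule enzymes (3.30 ± 0.46 h), and the autophagy receptor SQSTM1 (3.85 ± 0.66 h, 19.5 h over 0 to 2 h alone). At the slow end GRN had 17.2 h and LAMP1 18.0 h, each with a fit at the limit of 1000 h in some alternative. Camera gave adjusted p = 2.72e-05, and adjusted p = 0.453 with an estimated correlation (1.79e-08 to 0.453 over 11 alternatives). Myeloid granule and surface markers declined in 19 of 29 with a median of 4.78 h over those 19 genes (3.15 to 11.9 h, percentile 98.82). The median of all 29 genes of the list kept 60.64% of its labelled share of the 0 to 40 min libraries at 8 h and 48.39% at 12 h. The lipopolysaccharide receptors CD14 (1.59 ± 0.32 h) and TLR4 (1.94 ± 0.35 h) were its fastest members. The list was called slower with adjusted p = 2.47e-11, and adjusted p = 0.350 with an estimated correlation (1.7e-13 to 0.350 over 11 alternatives). Glycolysis genes declined in 13 of 18 (11 adjusted over the list alone) with a median of 5.35 h over 10 resolved genes (2.91 to 10.2 h, percentile 98.64). A further 3 lay above 24 h. The median of all 18 genes of the list kept 80.57% of its labelled share of the 0 to 40 min libraries at 8 h and 47.83% at 12 h. Its glucose transporters were its fastest members named (SLC2A3 1.81 ± 0.20 h, SLC2A1 2.86 ± 0.39 h, 7.87 h over 0 to 2 h alone) and pyruvate kinase, PKM, was slow (13.22 ± 1.51 h). Camera gave adjusted p = 4.49e-08, and adjusted p = 0.401 with an estimated correlation (2.69e-09 to 0.401 over 11 alternatives). With the 0 to 2 h libraries alone the half-life of PKM was 126 h.

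Cell-cycle lists lay between. Mitosis genes declined in 34 of 34 with a median of 2.87 h (2.29 to 3.27 h, percentile 8.36), above the 2.72 h of all genes and below the 3.31 h of matched genes. The kinesin CENPE (1.90 ± 0.21 h) and the kinase AURKA (1.92 ± 0.25 h) were fast and the kinase subunit CKS2 slow (5.59 ± 0.70 h, 3.35 h on CPM and 13.2 h over 0 to 2 h alone). Camera called the list faster (adjusted p = 0.015), and gave adjusted p = 0.732 with an estimated correlation and 0.197 on CPM (0.00395 to 0.732 over 11 alternatives). DNA replication genes declined in 37 of 38 with a median of 3.55 h (percentile 80.58, camera adjusted p = 0.726, 0.393 to 0.963 over 11 alternatives), with the licensing factor CDC6 at 1.73 ± 0.31 h and CCNE1 at 1.78 ± 0.28 h. Integrated stress response genes declined in 28 of 28 with a median of 2.93 h (percentile 42.15, adjusted p = 0.185, 0.0282 to 0.821 over 11 alternatives, the lowest a call as faster over 0 to 2 h). CHAC1 had 1.54 ± 0.29 h and the serine synthesis enzyme PHGDH 10.11 ± 1.57 h. Cholesterol genes declined in 23 of 23 with a median of 2.86 h (percentile 79.62, adjusted p = 0.931, 0.195 to 0.992 over 11 alternatives), with FDPS at 8.57 ± 1.72 h. Heat shock and chaperone genes declined in 25 of 25 with a median of 4.39 h (percentile 38.88, adjusted p = 0.508, 0.0326 to 0.93 over 11 alternatives, the lowest a call as slower over 0 to 2 h), with DNAJB1 at 1.75 ± 0.23 h. Interferon-stimulated genes declined in 25 of 26 with a median of 3.09 h (percentile 92.34, adjusted p = 0.508, 0.0311 to 0.881 over 11 alternatives, the lowest a call as slower on CPM), with IFI44L at 2.13 ± 0.25 h. The 7 genes measured of the snoRNA host and NMD list declined with a median of 2.40 h (percentile 20.20, adjusted p = 0.248, 0.181 to 0.732 over 11 alternatives), the snoRNA host TAF1D at 2.19 ± 0.27 h. Among histones, whose replication-dependent mRNAs lack poly(A) tails, 2 of 4 declined and HIST1H4C had 2.62 ± 0.43 h. Camera called them slower (adjusted p = 6.22e-05), and gave adjusted p = 0.195 with an estimated correlation (9.05e-06 to 0.740 over 11 alternatives). On the DNA replication, cholesterol and heat shock lists, camera leaned the opposite way from the median among matched genes, without a call over the whole chase. Adjusted over the list alone, the counts of declining genes equalled those given here except where stated. Markers of lymphoid, erythroid and epithelial cells had too few reads for this test (0 tested), and mitochondrially encoded mRNAs and the listed nuclear RNAs were not analysed here.

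**Figure D2:**
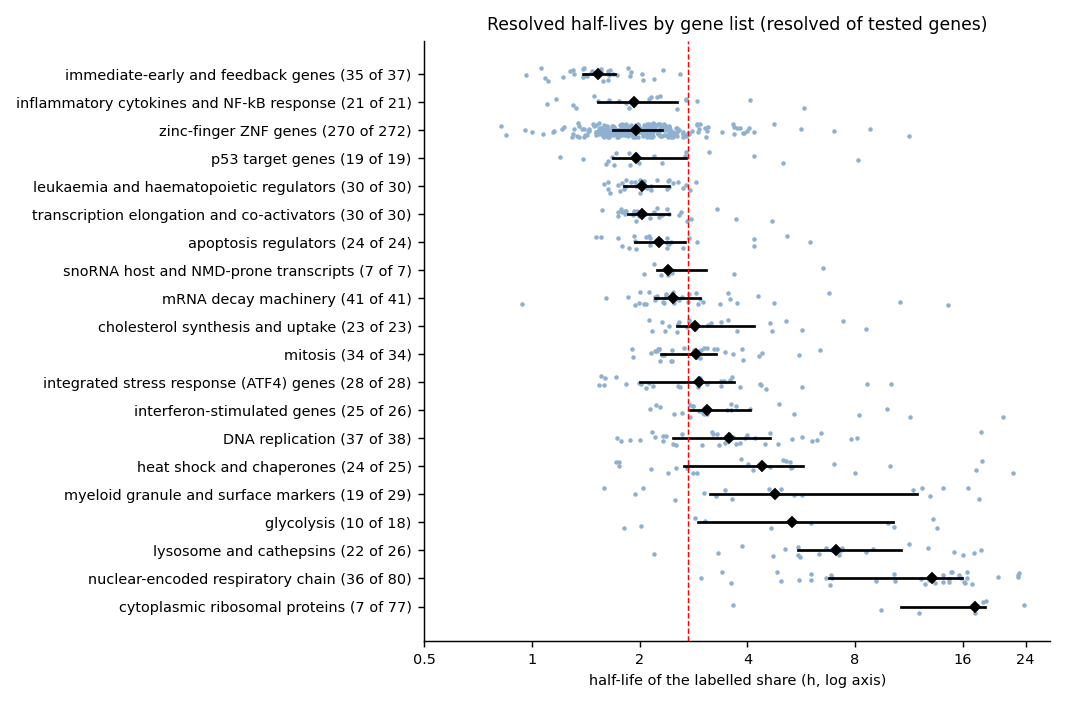
Resolved half-lives in hours (log axis) of the genes in 20 lists, with median (diamond) and interquartile range (bar) per list and the median of all genes, 2.72 h, as a dashed line. Medians run from 1.53 h for immediate-early genes to 17.3 h for ribosomal protein genes, of which 7 of 77 tested were resolved.

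Decay rates from labelled shares assume level totals, so total reads were tested for a trend over the same 7 libraries. The largest changes given here are those among called genes with a mean count of at least 100. The largest increases were in RIPOR2 (4.33 ± 0.19 log2 over 12 h, adjusted p = 3.13e-09, edgeR), and in OLIG1 and OLIG2, transcription factors of the oligodendrocyte lineage (3.95 ± 0.26 and 2.75 ± 0.14). CCL2, the monocyte chemoattractant (2.86 ± 0.21), NAV3 (2.82 ± 0.17), the stress-response gene IER3 (2.75 ± 0.35), the ubiquitin ligase HERC4 (2.69 ± 0.20) and IL1B, which encodes interleukin-1 beta (2.60 ± 0.39), rose too. The largest decreases were in ALDOC, an aldolase (-2.64 ± 0.27, adjusted p = 3.67e-06, edgeR), MS4A3, a membrane protein of myeloid progenitors (-2.51 ± 0.14), STAR, which moves cholesterol into mitochondria (-2.48 ± 0.26), TET2, which oxidises methylcytosine (-2.47 ± 0.34), MYADM (-2.47 ± 0.72), the repressor BHLHE40 (-2.40 ± 0.53), the antisense RNA PYCARD-AS1 (-2.40 ± 0.25) and the dendritic-cell marker CD83 (-2.38 ± 0.43). In all, 5474 of 10643 genes changed (51.4%), 2929 upwards and 2545 downwards, with a median size of 0.70 on the log2 scale, and 840 rose and 512 fell at least 2-fold. Of the calls 53.5% were increases, against 68.1% with library-size scaling (3816 and 1791). Among the 2351 genes with the lowest 0 h labelled share, up to 29.79%, 344 rose and 972 fell, and among the next 2350 genes 841 rose and 431 fell. With shares of 44.52% to 56.17%, 886 rose and 368 fell. In the 2351 genes above that, up to 84.73%, 640 rose and 605 fell (median 0.01), so the balance did not climb steadily with the share. Segments begin (hg19) at 24804513 of chromosome 6 for RIPOR2 (minus), 34443369 of chromosome 21 for OLIG1 (plus), 26900133 of chromosome 17 for ALDOC (minus) and 59837707 of chromosome 11 for MS4A3 (plus).

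Cytoplasmic ribosomal protein genes fell in 75 of 78, none rose (the same counts adjusted over the list alone), and the median was -0.58. RPL13A fell by 1.11 ± 0.08 on the log2 scale. Camera called the list lower (adjusted p = 1.07e-19), and gave adjusted p = 0.318 with an estimated correlation. Respiratory-chain genes fell in 64 of 80 and rose in 4 (same adjusted over the list alone), among them the ATP synthase subunits ATP5MC2 (-0.71) and ATP5MC1 (-0.74), with adjusted p = 3.44e-10, and adjusted p = 0.478 with an estimated correlation. Glycolysis genes fell in 10 of 18 and rose in 3 (same adjusted over the list alone), with LDHA at -0.82 (adjusted p = 0.0378, and adjusted p = 0.508 with an estimated correlation). DNA replication genes fell in 18 of 39 and rose in 7 (19 and 7 adjusted over the list alone), among them MCM7 (-0.83), RRM2 (-0.90) and CCNE2 (-1.32), with adjusted p = 0.0378, and adjusted p = 0.326 with an estimated correlation. Library-size scaling evened that split to 11 lower and 10 higher. Myeloid markers fell in 13 of 30 and rose in 5 (same adjusted over the list alone), the neutrophil proteases PRTN3 (-1.74) and CTSG (-1.61) among them (adjusted p = 0.0356, and adjusted p = 0.700 with an estimated correlation). ZNF genes fell in 95 of 360 and rose in 55 (90 and 52 adjusted over the list alone), for example ZNF614 (-1.81), with adjusted p = 0.0356, and adjusted p = 0.316 with an estimated correlation. With library-size scaling the ZNF split turned over to 71 lower and 74 higher.

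Inflammatory and NF-kB genes rose in 16 of 22 and fell in 2 (same adjusted over the list alone), with a median of 1.08. PLAUR, the urokinase receptor, rose by 2.18 (log2 over 12 h) and the adhesion molecule ICAM1 by 1.15, and camera gave adjusted p = 0.00245, and adjusted p = 0.316 with an estimated correlation. Leukaemia and haematopoietic regulators rose in 17 of 32 and fell in 1 (same adjusted over the list alone), GFI1 by 1.81, CEBPB by 1.20 and IRF8 by 1.00 (adjusted p = 0.0218, and adjusted p = 0.316 with an estimated correlation). Elongation factors and co-activators rose in 17 of 30 and fell in 4 (18 and 4 adjusted over the list alone), with MED1 at 0.99 and BRD2 at -1.07 (adjusted p = 0.0356, and adjusted p = 0.447 with an estimated correlation). The remaining lists were not called by camera. Immediate-early genes rose in 7 of 39 and fell in 6 (7 and 3 adjusted over the list alone), with FOSL2 at 1.78. Mitosis genes rose in 10 and fell in 5 of 34, with CKS2 at -1.54 and the cyclin CCNB1 at -0.85. Apoptosis regulators rose in 10 and fell in 8 of 25 (11 and 4 with library-size scaling), with BCL2A1 at 1.15. p53 targets rose in 4 and fell in 4 of 20 (6 and 2 with library-size scaling, 4 and 5 with DESeq2 factors), with GADD45A at -1.37 and CDKN1A at 0.66. Of integrated stress response genes 10 rose and 7 fell of 28 (12 and 3 with library-size scaling), of cholesterol genes 3 rose and 8 fell of 23 (5 and 3 with library-size scaling), and of heat shock genes 7 rose and 6 fell of 25 (11 and 6 with library-size scaling). SLC3A2 (-0.97), the isomerase IDI1 (-0.65) and the calcium-binding chaperone CALR (-0.95) were members that fell. Of lysosome genes 6 rose and 7 fell of 27 (13 and 4 with library-size scaling), of decay-machinery genes 14 rose and 11 fell of 42 (13 and 13 with DESeq2 factors, 19 and 8 with library-size scaling), of interferon-stimulated genes 5 rose and 9 fell of 27, of the snoRNA host and NMD genes 2 fell of 7, and of histones 3 fell of 6. The scaffold CNOT1 rose by 1.01, and IRF9 (-1.96) and IFIT3 (-2.01) fell. Adjusted over the list alone, 11 and 8 apoptosis regulators, 17 and 13 decay-machinery genes and 6 and 6 lysosome genes rose and fell, and counts of the other uncalled lists were as given. Medians of the interferon-stimulated (0.05), lysosome (0.06) and snoRNA host (0.12) lists lay above 0 where camera leaned lower, without a call. None of 5 markers of other cell types was called, GNLY, HBG1 and HBG2 among them, but HBG1 and HBG2 were called higher without the 8 h library (adjusted p = 0.0123 and 0.0292, edgeR).

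**Figure D3:**
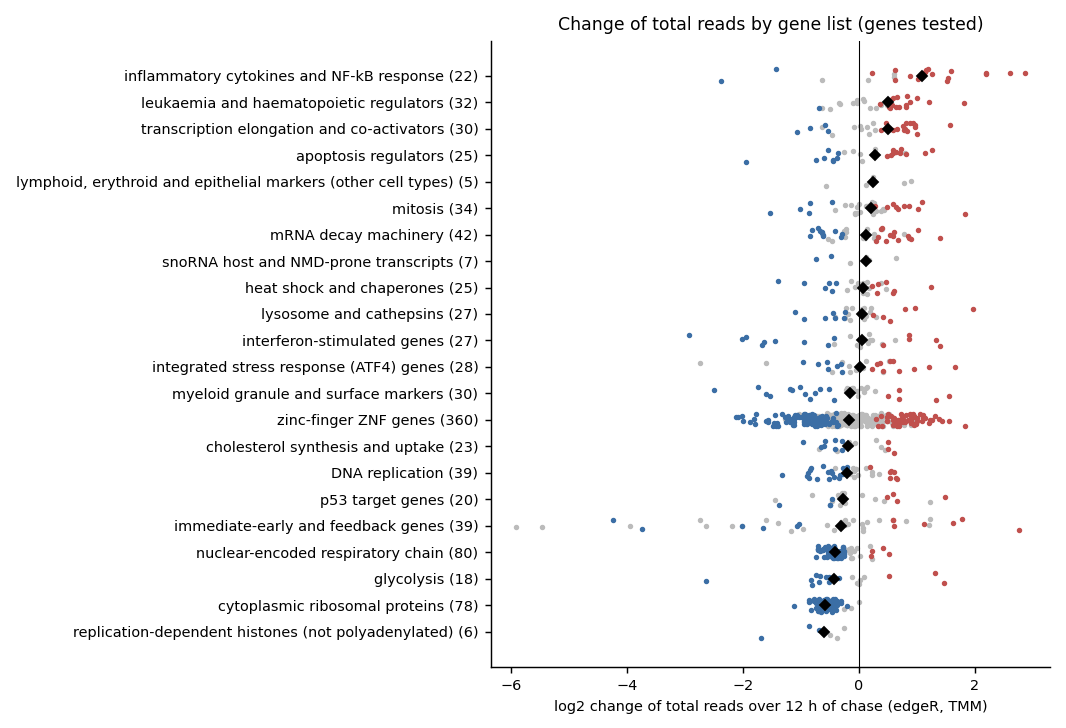
Change of total reads over 12 h of chase (log2, edgeR with TMM) for each gene of 22 lists, coloured red (higher) or blue (lower) where the adjusted p was under 0.05, with list medians as diamonds. Ribosomal protein genes fell in 75 of 78 and inflammatory genes rose in 16 of 22, and the splits of ZNF, cholesterol and lysosome genes turned over with library-size scaling.

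Without the 12 h library BHLHE40, IL1B and MYADM were not called (adjusted p = 0.0781, 0.0591 and 0.340, edgeR; over all alternatives 1.86e-09 to 0.301, 2.65e-09 to 0.203 and 3.67e-05 to 0.545), nor was MYADM without the 40 min, 1 h or 8 h library (0.056, 0.0708 and 0.081), and TET2 was at 0.14 (log2, adjusted p = 0.491) with its segments summed. With ranked times 19 of 78 genes picked by the naming rule for totals lost their call, among them TET2 (adjusted p = 0.0503), IL1B (0.0649), ALDOC (0.065), IER3 (0.0653), CD83 (0.229), BHLHE40 (0.301) and MYADM (0.545). Adding the library without 4sU as another 0 h left 182 higher and 127 lower genes, and the 0 to 2 h libraries alone gave 480 and 178, of which 152 and 88 were among those called over 12 h.

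**Figure D4:**
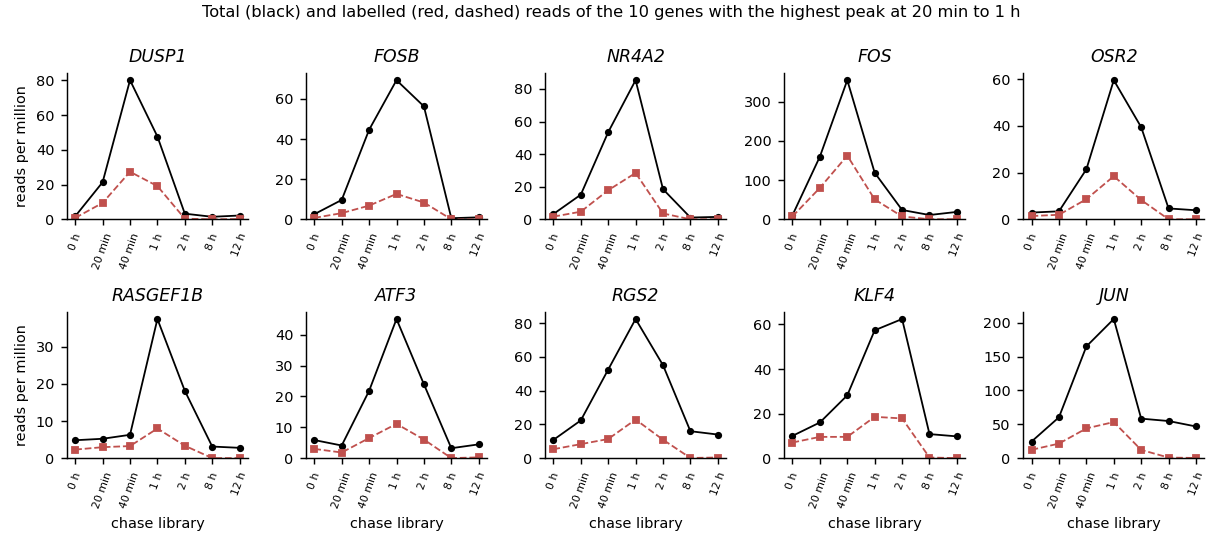
Total (black) and labelled (red, dashed) CPM in the 7 chase libraries for the 10 genes with the highest peak at 20 min to 1 h over both 0 h and 12 h, chosen after their values were seen. FOS reached 355 CPM at 40 min from 10.3 at 0 h, a course that a straight line in time does not describe.

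Whether the 12 h pulse went with other RNA levels was asked from the 0 h library and the library without 4sU. At 0 h, C3, a complement component, was at least 35.5-fold higher (lower end of the counting interval, 0 reads without 4sU, 393 at 0 h), the chemokine gene CXCL14 174-fold higher (counting interval 31.2 to 6902, 1 against 521 reads), ICAM1 91.7-fold (25.3 to 759, 2 against 548 reads), the calprotectin subunit S100A8 36.6-fold (28.1 to 48.7) and CCL2 at least 23.9-fold (0 against 265 reads). Lower at 0 h were GFI1 (18.8-fold, 16.3 to 21.7), the pro-apoptotic BIK (13.1-fold, 10.1 to 17), TMEM250 (12.3-fold, 11 to 13.8), the channel-like TMC6 (12.1-fold, 10.2 to 14.3) and CEBPA, the granulocyte-monocyte transcription factor (8.73-fold, 8.35 to 9.13). Of 6877 genes measured, 807 (11.7%) were more than 2-fold higher at 0 h and 804 (11.7%) more than 2-fold lower, counting genes whose interval lay wholly past that fold. With 1 library on each side and no replicate, no p-value can be given. Segments begin (hg19) at 6677715 of chromosome 19 for C3 (minus), 153362508 of chromosome 1 for S100A8 (minus), 92940321 of chromosome 1 for GFI1 (minus) and 33790840 of chromosome 19 for CEBPA (minus). The library without 4sU stood apart from every other: its correlation with a chase library was at most 0.942, against 0.978 to 0.996 among chase libraries, and the median absolute log2 ratio to 0 h was 0.68, against 0.08 between 0 h and 20 min and 0.34 between 0 h and 12 h.

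Interferon-stimulated genes were higher at 0 h in 13 of 18 and lower in none, with a median of 8.22-fold (percentile 100 among matched random lists). OAS1 was 43.2-fold (11.8 to 358, 2 reads without 4sU), the antiviral GTPase MX1 24.5-fold (11.2 to 67.1) and IRF9 24-fold higher. Inflammatory genes were higher in 9 of 15 and lower in 1, with a median of 4.34-fold (percentile 100). With the gene at 0 reads set to 3 reads the median was 5.05-fold. The NF-kB inhibitor TNFAIP3 was 27.1-fold higher. IL1B, below the count minimum and not among the 15, was at least 17.2-fold higher (0 against 191 reads). Myeloid markers were higher in 14 of 26 and lower in 1 (median 2.45-fold, percentile 100), with the signalling adaptor TYROBP at 14.6-fold and LYZ at 9.29-fold. Respiratory-chain genes were higher in 22 of 78 and lower in 1 (median 1.57-fold, percentile 99.99). Ribosomal protein genes were higher in 24 of 76 and lower in 2 (median 1.52-fold, percentile 99.81) and went both ways: RPS6 was 5.79-fold and RPL14 5.72-fold higher, and RPLP2 2.66-fold and RPL5 2.29-fold lower. Immediate-early genes split 6 higher and 6 lower of 27 around a median of 1.55-fold lower (percentile 0.38), EGR1 at 7.44-fold and IER2 at 7.03-fold lower. Leukaemia and haematopoietic regulators were higher in 2 and lower in 7 of 28 (percentile 4.41), and cholesterol genes lower in 4 of 13 and higher in none (percentile 5.24).

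In the other lists, counts of higher and lower genes were 18 and 12 of 131 ZNF genes, 2 and 1 of 15 glycolysis genes, 2 and 6 of 33 mitosis genes, with TOP2A 8.43-fold lower, and 0 and 3 of 38 DNA replication genes. They were 1 and 3 of 20 apoptosis regulators, 3 and 1 of 15 p53 targets, 6 and 4 of 24 stress response genes, 3 and 4 of 24 heat shock genes and 4 and 3 of 24 lysosome genes. Among snoRNA host and NMD genes 1 of 6 was higher, among elongation factors 2 were higher and 4 lower of 23, among decay-machinery genes 5 and 3 of 36, and of 2 histone genes 1 was lower. Markers of other cell types did not reach the count minimum. TMM scaling shifted all ratios alike by 0.01 on the log2 scale.

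**Figure D5:**
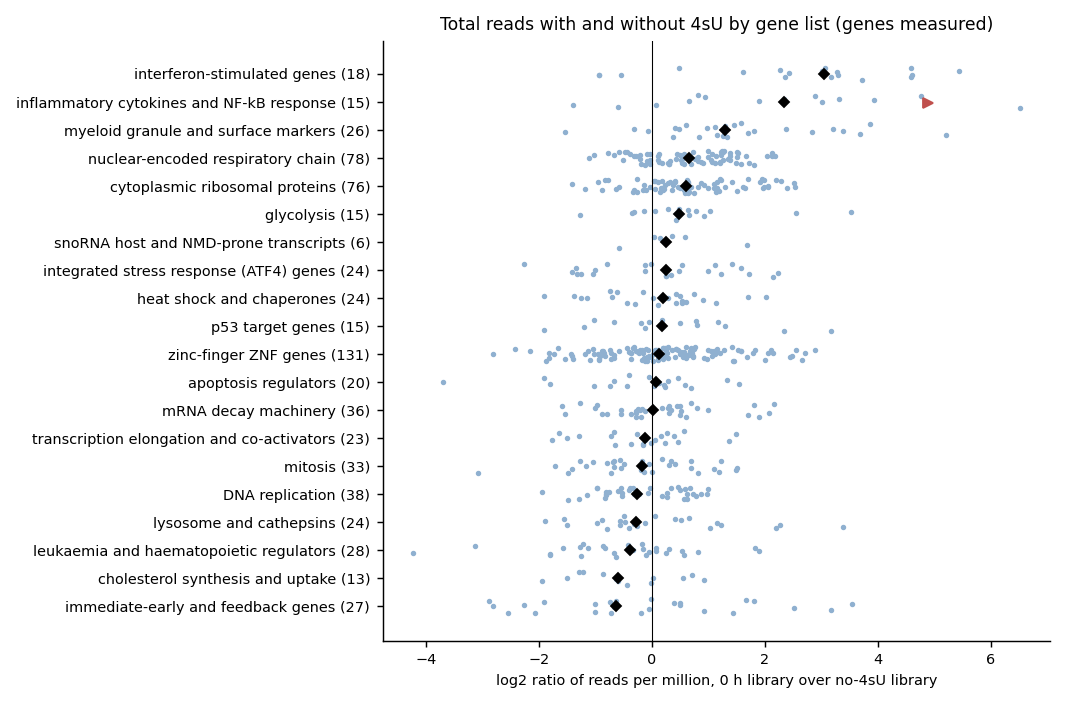
Log2 ratio of CPM in the 0 h library over the library without 4sU for each gene of 20 lists (points), with list medians as diamonds and a triangle where the library without 4sU held no read, with the point drawn as the ratio to 3 reads. Interferon-stimulated genes have a median of 8.22-fold higher at 0 h, and immediate-early genes lie on both sides of 0.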

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

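Chosen only after the result was seen were the tests of incorporation after the wash, of the labelled share against total change, of the labelled share of genes higher at 0 h, and of library preparation. In the 0 h library, 34.15% of reads in 11504 segments without a matched gene were labelled (95% exact interval 34.07 to 34.24, 402847 of 1179587 reads), against 0.01853% without 4sU (0.01462 to 0.02316, 77 of 415541 reads). These segments entered no comparison in the results. Whether they hold the same reads as segments of genes analysed was not tested.

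The labelled share over all genes was 30.6% at 0 h and 30.2% at 1 h, although many transcripts had lost their label by 8 h. Stable transcripts dominating the average would need short-lived genes to have lost label by 1 h, to 75% of the 0 h share or less. A set of 1879 genes had under 5% of their labelled share of the 0 to 40 min libraries left at 8 h. Their median 1 h share was 85.9% of the 0 h share (bootstrap interval 85 to 86.8). That is above the 75% and barely above the 85% set as arguing against stable transcripts. The interval reaches 85% and resamples genes, so it leaves out differences between the libraries, 1 per time. Stable transcripts as part of the cause therefore stay open. Label still entering new RNA after the wash may hold the share level: labelled CPM was higher at 40 min than at 0 h in 100% of the 22 genes whose totals were at least 2-fold higher, with a median of 2.08-fold. No biological explanation was tested.

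Total levels moved over the chase in 5474 genes. Loss of labelled reads before counting could lift genes with much label as the label goes: Spearman's rho across 9402 genes between the 0 h labelled share and the change over 12 h was 0.12, under the 0.3 such a loss would give and above the 0.1 that would argue against it. Holding that share fixed, rho with the T content of the last 300 bases was 0.09, between the bounds of 0.05 and 0.1 set for it, so loss of uridine-rich reads stays open too. Neither can be told apart from a response to the wash, the fresh medium or the uridine, since every chase library received these, and that response stays open as untested.

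Levels at 0 h differed from those without 4sU in both directions. Loss of labelled reads before counting would lift genes with little label in relative terms. Of 806 genes more than 2-fold higher at 0 h, 37.3% lay above the median labelled share, between the 25% such a loss would give at most and the 40% that would argue against it. It therefore stays open for those with little label, and by itself would not lift those above that median. The test on these 806 genes replaced a limit on the composition shift that was computed from the share left after any such loss and could exclude nothing. For the genes lower at 0 h, rho between labelled share and ratio was -0.04 across 6872 genes, and 47.7% of 803 lower genes lay above the median share. That argues against such a loss as the main cause of these lower levels. A smaller loss is not excluded, since the wide spread between these libraries (median absolute log2 ratio 0.68) could hide it. Genes at least 4-fold higher at 20 min than without 4sU changed by a median of -0.16 (log2, interquartile range -0.53 to 0.30, 323 genes) from 0 h to 12 h, between the -0.5 of a reversing response and the -0.1 of none, so a response to the pulse stays open. Genes lower at 0 h were not tested for reversal. Each gene named above as lowest at 0 h was higher at 12 h, for example GFI1 (25.8 and 102 CPM) and CEBPA (296 and 466 CPM). Both stayed below their levels without 4sU (485 and 2587 CPM). These genes were picked by their 0 h level, so their rise is no test. Preparation of the single library without 4sU is a candidate explanation, since ribosomal protein genes scattered 6.91 times as widely (SD of log2 ratios 0.93 over 76 genes) between 0 h and no 4sU as between 12 h and 0 h (0.13), and the labels give no batch to separate it from 4sU itself.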

How the results depend on the processing

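Added after seeing the data were the 1 to 12 h window, summed segments, and the 0 to 2 h window for totals. No paired analysis was possible because each condition has 1 library. Outside the 0 to 2 h window, 5980 genes (of 6319 with a mean count of at least 200) to 11410 (of 14016 with at least 1 labelled read) declined, against 8957 of 9402, with 8518 (without the 12 h library) to 8980 leaving out each chase library, and the median half-life ran from 2.34 h (1 to 12 h) to 3.38 h (unweighted), with leave-one-out values of 2.58 to 2.98 h. With the 0 to 2 h libraries alone 3023 genes declined, as 5 libraries over a short window hold less decay, and the median half-life was 3.01 h. Over that window the leukaemia list's median turned from below to above that of all genes resolved there (0.20 log2, 22 members). That of mRNA decay machinery came level with it (0.00, 21 members). Only 2822 genes were resolved over that window, against 8832, so these medians rest on another set of genes. Camera, which used all genes tested, still separated both lists over that window. The cause of the turn was not tested. Counts of lists separated by camera ran from 11 to 15, against 12, and fell to 1 with an estimated correlation. Totals gave 2534 to 2922 higher and 2247 to 2676 lower genes leaving out each chase library, 3816 and 1791 with library size, 1690 and 1133 with ranked times, 182 and 127 with the library without 4sU as another 0 h, and 480 and 178 over 0 to 2 h, a window of fewer libraries. The cause was otherwise not tested. Over 0 to 2 h BHLHE40 rose, with a slope extrapolated to 4.29 (log2 over 12 h). The share of labelled reads was 0.009809% without 4sU when genes above 5% were left out, and 30.55% (0 h) and 5.554% (12 h) with a mean count of at least 50, since other genes were summed. Against no 4sU, 792 to 822 genes were higher and 782 to 804 lower. For named genes, half-lives stayed within their error in 1349 combinations of gene and setting and moved in 145 (68 longer and 2 shorter over 0 to 2 h, 19 and 15 on CPM, 16 longer without the 12 h library), and total trends kept call and direction, or stayed without a call in either direction, in 1000, lost the call in 162 (65 over 0 to 2 h, 60 with the library without 4sU as another 0 h, 19 with ranked times), gained it in 4 and turned in 1 (BHLHE40). Of the 8 libraries the one without 4sU is the shallowest, with 2916031 reads.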

Other observations

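The transient peaks, their test and the reassignments of chase times were chosen after the result was seen. Several immediate-early genes were many times higher in the first hour after the wash than at 0 h and at 12 h. FOS, an AP-1 subunit induced within minutes of growth signals, stood at 10.3 CPM at 0 h, 355 at 40 min (90 and 3384 reads) and 18.8 at 12 h. DUSP1, a phosphatase that switches off MAP kinases, reached 46.5 times its 0 h level at 40 min, FOSB 27.5 times and the nuclear receptor NR4A2 26.6 times at 1 h. ATF3 (7.7 times) and JUN (8.4 times) peaked at 1 h. KLF4 stood at 5.75 times its 0 h level at 1 h and was higher again at 2 h (62.4 CPM). Peaks outside the immediate-early list were those of NR4A2, of OSR2, a zinc-finger developmental factor (15.4 times the higher of 0 h and 12 h), RASGEF1B, an exchange factor for RAP GTPases (7.78 times), and RGS2, a brake on G-protein signalling (5.9 times).

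Labelled reads were higher at these peaks too. Labelled FOS CPM was 22.1-fold higher at 40 min than at 0 h, with labelled shares of 45.7% and 71.1%, and labelled CPM at the peak was 34.0-fold higher for DUSP1, 18.4-fold for FOSB and 17.7-fold for NR4A2. FOS was 0.64% labelled at 12 h.

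A general shift of the early libraries could have produced such peaks in any list. Of 34 immediate-early genes measured, 6 peaked at least 4-fold over both 0 h and 12 h, against 10 of all 8120 genes, which argues against such a shift. Of 10000 random lists of like abundance 0.00% held as many (the highest held 2). As the peaks were seen first, the random lists restate them and are no independent test. A response of signalling to the wash and the fresh medium is a hypothesis that these libraries alone leave untested.

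The trends in time were set against other assignments of the 7 times to the 7 libraries, with a simpler edgeR fit. As many declining genes came from 1 of 40 assignments, the real one (8963 genes, highest other 8869), and as many changes of total level from 1 of 40 (5463, highest other 5291). These counts rest on the late libraries: the 4 other assignments that kept the 8 h and 12 h libraries late gave at least 7318 and 4713 genes, and assignments that did not gave 0. Among those 4, the assignments with the early times in a largely turned order (correlations of -0.56 and -0.51 with the real order) gave 8846 and 8869 declining genes and 5260 and 5291 changes of total level, so the counts set the late libraries apart from the early ones and leave a trend within the early libraries open.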
